A study of Homo sapiens with 6 samples.

How the data were processed

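RNA was measured in 6 libraries of MDA-MB-231BR cells, a brain-tropic derivative of the human breast cancer line MDA-MB-231. Of these, 3 libraries came from cells stably expressing a control short hairpin RNA (shRNA) and 3 from cells expressing an shRNA against ACSS2. Per the labels, mRNA was enriched with oligo(dT) beads and sequenced at BGI on DNBSEQ, and the libraries of each group are biological replicates. They do not state how many hairpin sequences were used, so whether the numbers 1 to 3 stand for replicates of the same hairpin or for different hairpins is open. The submitters' processing notes name HISAT, Bowtie2 and RSEM without versions. The annotation behind the gene table is not given in the sources used here. Chromosome accessions in the table belong to GRCh38, and coordinates are given on that build.

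The deposited table holds expected counts, which are the estimated reads per gene from the authors, in 6 columns. It also holds TPM columns made by the authors. The authors further deposited their own comparison of the groups by DESeq2, as a log2 fold change with a p-value and a q-value, which is NA for 860 genes. Its version and settings are not given in the sources used here. The 6 FPKM columns of the table were not used. Between 10.47% and 13.01% of the expected counts in a library were not whole, and they were rounded to whole counts. The table lists 17721 genes, of which 797 had 0 counts in all 6 libraries. Before use, 565 lines of annotation text that had spilled out of their cells were left out, and 26 gene symbols that a spreadsheet had turned into dates were restored from their gene IDs. Of the gene IDs, 17479 were found in a reference table of gene names.

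Total counts were between 15048275 and 18608124 per library, and between 15062 and 15465 genes had counts above 0. The tests below take counting error and the spread between replicates together.

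The comparison of ACSS2 shRNA with control shRNA used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the default low-count filter (filterByExpr, minimum count 10 and minimum total count 15). This left 13003 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The test has no replicate term, and is named the unpaired fit. The labels carry a batch tag that numbers the libraries 1 to 3 in both groups, so the same test was run with the replicate number as an additive block, named the paired fit. The pairing was checked in the counts. Deviations from the group mean of log2 CPM (counts scaled by library size) correlated across genes by 0.716, 0.494 and 0.740 between libraries with the same number, against a required minimum of 0.1. Between libraries with different numbers the highest value was -0.01. Centering each group on its own mean pulls these values below 0 when the same-number values are above it. Genes are not independent replicates in these correlations. Because the block changes most calls, both fits are reported. Levels are CPM scaled with the TMM factors, given as mean ± SD of 3 libraries. Log2 fold changes are ACSS2 shRNA over control shRNA, and their standard errors (SE) are the absolute log2 fold change divided by the square root of F.

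Gene sets were 24 lists for pathways and cell states and 5 lists of markers for other cell types. Of their 625 entries, 619 were found in the table. The pathway lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and p was adjusted by Benjamini-Hochberg over the 24 lists. Each test was repeated with the correlation estimated per list and with fry of limma. With 6 libraries an estimated correlation leaves few degrees of freedom. Its smallest adjusted p over the 24 lists was 0.161 unpaired and 0.695 paired, so no list passed there in either fit. The estimates themselves differed between lists. Unpaired they were 0.919 for mitosis, 0.868 for E2F targets and 0.69 for ribosomal proteins, far above the preset, and paired 0.652, 0.753 and 0.768. For these lists camera p with the preset correlation is likely too small. For the other called lists described below they lay between 0.00322 and 0.085 unpaired, and between 0.032 and 0.188 paired. Camera asks whether the genes of a list are higher or lower than other genes. Fry asks whether they move, on balance, one way. Counts of list members are given over all genes tested and adjusted over the list alone.

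Genes named in the text follow a rule. ACSS2, E2F1, SLC7A11 and GPX4 are always given. To these come the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. From each called pathway list, from both ferroptosis lists, from the glutathione list and from the list of E2F targets, the 3 members with the smallest p are given, and from every other pathway list the member with the smallest p. The p used to pick list members is that of the unpaired fit, also where paired values are printed. Not every item this rule picks is reported here. The groups, the unpaired fit, the block as its alternative, the lists, this rule and most alternatives were chosen before the data were examined. The same choice of 8 higher and 8 lower genes in the paired fit, the alternatives to the paired fit, the length and GC correction and the site counts were added after the data were seen.

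Alternatives were DESeq2 size factors, total counts or upper quartile factors in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, limma on log2 TPM with a pseudocount of 1 or 0.1, no low-count filter, a filter of 5 CPM, stricter thresholds (adjusted p under 0.01, or a change of at least 2-fold) and leaving out each library or each replicate number. For the length and GC correction, a trend on transcript length and GC content (natural splines with 5 degrees of freedom each) was removed from each library.

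Transcript sequences came from GENCODE 29, with 1 coding transcript per gene, a principal one where annotated. In a scan of 12667 genes with a 3′ UTR of at least 20 bases, the log2 fold change of the paired fit was regressed on the presence of each of 16380 7-mers found in at least 20 genes. The regression held UTR length, transcript length and GC content constant. Its p-values were Bonferroni-adjusted, and the highest absolute t was compared with that of 100 permutations of the genes. Matching used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

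Both fits were tested on simulated data for 13003 genes with 100 genes changed by 2-fold and 100 by 4-fold. The unpaired fit recovered 22% and 82% of them, with 8 false calls among 112. The paired fit, on simulated data with replicate differences, recovered 87% and 97%, with 7 false calls among 191. A single shifted list was the only list called in both, but genes were simulated independently of each other. This does not measure false list calls where members are correlated, as in the mitosis list (estimated correlation 0.919 unpaired and 0.652 paired). In the 7-mer scan, a planted effect of -0.20 was recovered as -0.18 and ranked lowest. With none planted, 1 7-mer passed the Bonferroni threshold, so the permutations are given beside it.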

Results

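MDA-MB-231BR cells carrying a control shRNA were compared with the same line carrying an shRNA against ACSS2, the nucleocytosolic enzyme that makes acetyl-CoA from acetate. Each group had 3 libraries. The series title connects ACSS2 with E2F1, SLC7A11 and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. The comparison asks which transcripts differ when ACSS2 is targeted, and whether those of E2F1, SLC7A11 and other ferroptosis genes are among them. Total counts of control replicates 1, 2 and 3 were 18608124, 16869062 and 16093086. Those of ACSS2 shRNA replicates 1, 2 and 3 were 17520166, 15048275 and 16548431. Log2 CPM correlated by 0.934 to 0.982 between libraries across genes, which are not independent replicates. The first principal component (44.4% of variance) followed the replicate number and the second (29.9%) separated the groups. In the paired fit, 5030 genes differed between replicate numbers.

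**Figure D1:**
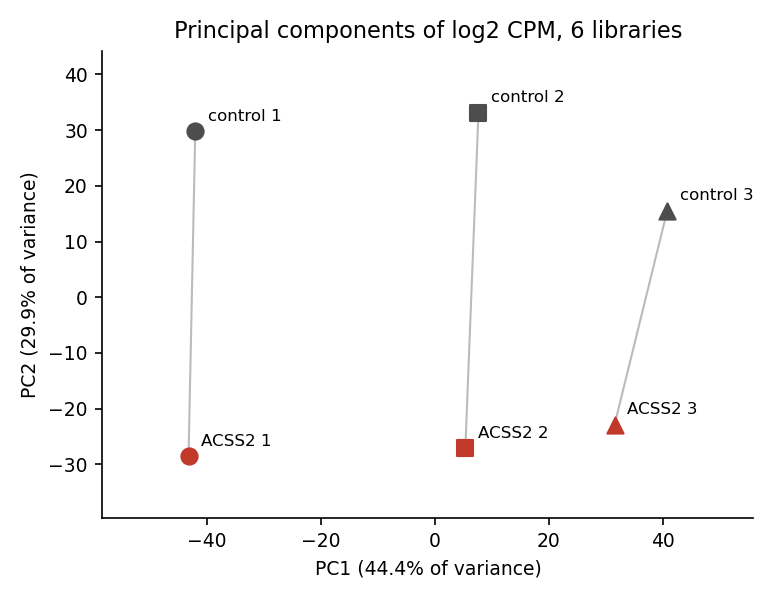
Principal components of log2 CPM, with a point for each of the 6 libraries. The first axis (44.4% of variance) follows the replicate number and the second (29.9%) parts ACSS2 shRNA from control shRNA.

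ACSS2 mRNA was lower in the ACSS2 shRNA library of every replicate number, and fell 2.48-fold in the paired fit. Its level was 104 ± 52.0 CPM (SD, n = 3) in control and 50.1 ± 38.8 CPM in ACSS2 shRNA cells. E2F1, a transcription factor that drives entry into S phase, was 40.1 ± 21.6 CPM in control and 25.95 ± 7.10 CPM in ACSS2 shRNA cells, and fell 1.44-fold in the paired fit. SLC7A11, the cystine importer that feeds glutathione synthesis, was 40.1 ± 17.1 CPM in control and 27.1 ± 4.32 CPM in ACSS2 shRNA cells, and passed the test in neither fit. GPX4, the glutathione peroxidase that removes lipid peroxides, was 421 ± 57.5 and 493 ± 44.4 CPM, and also passed in neither.

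ACSS2 (gene ID 55902, chromosome 20, 34866614 to 34955813, band 20q11.22) had 76.3, 71.2 and 163.6 CPM in control replicates 1, 2 and 3 and 11.1, 50.5 and 88.7 CPM in ACSS2 shRNA replicates 1, 2 and 3. The groups overlap, since ACSS2 shRNA replicate 3 lies above control replicates 1 and 2. Its log2 fold change was -1.05 (SE 0.64, edgeR adjusted p = 0.504) unpaired and -1.31 (SE 0.30, adjusted p = 0.00757) paired. The unpaired value was -0.56 without control replicate 3, -0.59 without ACSS2 shRNA replicate 1 and -1.75 without ACSS2 shRNA replicate 3, and passed in none of these. The paired call was lost with DESeq2 and the block (-1.38, adjusted p = 0.129), and without replicate 1 the paired value was -0.70 (adjusted p = 0.00249). The 3′ UTR of ACSS2 holds 1 copy of the sequence TGGGTC.

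E2F1 (gene ID 1869, chromosome 20, 33675486 to 33720308) had 61.4, 40.4 and 18.3 CPM in control and 31.5, 28.5 and 17.9 CPM in ACSS2 shRNA replicates 1, 2 and 3. Its log2 fold change was -0.63 (SE 0.41, adjusted p = 0.537) unpaired and -0.52 (SE 0.16, adjusted p = 0.0305) paired. Without 1 library or replicate number the unpaired value ranged from -0.97 (without control replicate 3) to -0.18 (without control replicate 1) and did not pass. The paired call was lost without replicate 1 (-0.29, adjusted p = 0.172), without replicate 2 (-0.56, adjusted p = 0.0545) and with limma on log2 TPM (-0.38, adjusted p = 0.0762, and -0.39, adjusted p = 0.0764, by pseudocount). SLC7A11 (gene ID 23657, chromosome 4, 138140032 to 138311434) had 20.5, 51.7 and 48.2 CPM in control and 24.3, 24.9 and 32.1 CPM in ACSS2 shRNA replicates 1, 2 and 3, so it was higher in pair 1 and lower in the other two. Its log2 fold change was -0.57 (SE 0.33, adjusted p = 0.484) unpaired and -0.48 (SE 0.19, adjusted p = 0.0840) paired. The same leave-outs gave unpaired values of -0.88 (without control replicate 1) to -0.32 (without replicate 2), none of which passed. With the block it passed without replicate 1 (-0.83, adjusted p = 0.00168), with no low-count filter (-0.50, adjusted p = 0.0230) and with the length and GC correction (-0.55, adjusted p = 0.0230), and without replicate 2 it was -0.22 (adjusted p = 0.518). Its 3′ UTR holds 3 copies of TGGGTC. GPX4 (gene ID 2879, chromosome 19, 1103926 to 1106789) had a log2 fold change of 0.23 in both fits (adjusted p = 0.596 unpaired and 0.170 paired), was 0.09 unpaired without control replicate 2, and passed only with limma on log2 TPM and the block (0.34, adjusted p = 0.0308 or 0.0302 by pseudocount). The 3′ UTRs of E2F1 and GPX4 hold no TGGGTC. In the authors' deposited comparison the log2 fold changes were -1.07 for ACSS2 (q = 0.772), -0.66 for E2F1 (q = 0.614), -0.59 for SLC7A11 (q = 0.565) and 0.20 for GPX4 (q = 0.894).

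**Figure D2:**
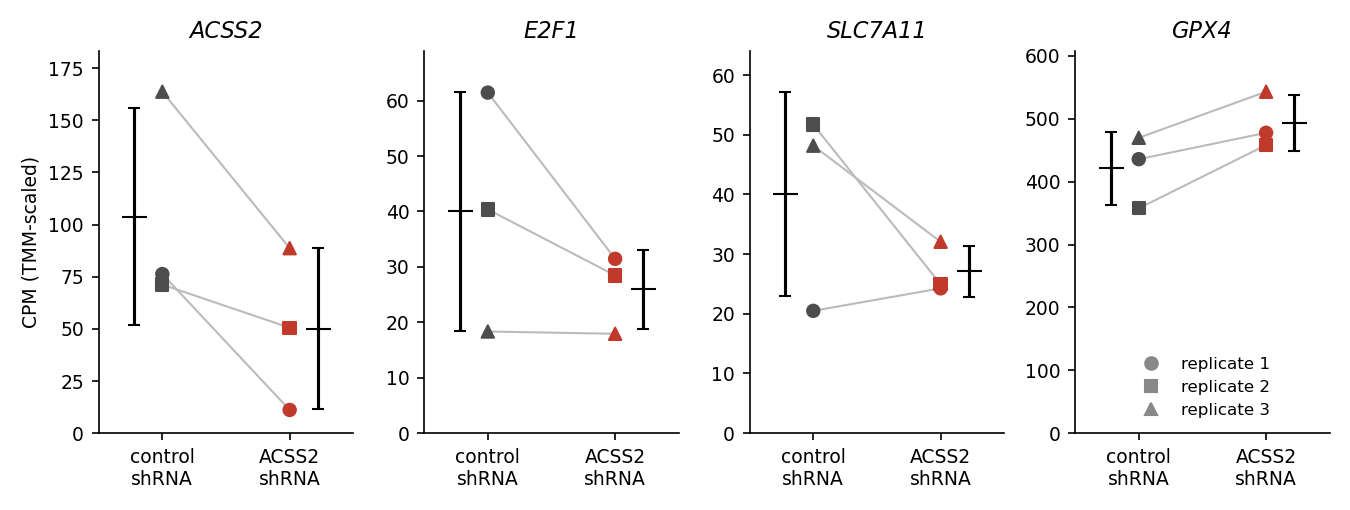
CPM of ACSS2, E2F1, SLC7A11 and GPX4 in each of the 6 libraries, with lines joining libraries of the same replicate number and bars for the mean ± SD of 3. ACSS2 is lower in every pair, E2F1 differs least in pair 3 (18.3 and 17.9 CPM), and SLC7A11 is higher in pair 1 (20.5 and 24.3 CPM).

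Across the transcriptome, complement factor B (CFB), the glycosyltransferase gene MGAT4B and SERPINA3 rose, and SNRPB2, R3HDM4, TIMM17B, TOMM34, TXN2 and S100A16 fell, even without the replicate block. CFB went from 7.77 ± 1.79 CPM (SD, n = 3) to 37.1 ± 7.94 CPM, and MGAT4B from 192 ± 25.6 to 532 ± 62.6 CPM. SNRPB2, which encodes a spliceosomal U2 snRNP protein, went from 87.1 ± 13.03 to 19.7 ± 2.36 CPM. TIMM17B, of the mitochondrial inner membrane import complex, went from 65.1 ± 5.28 to 19.7 ± 3.28 CPM, and TXN2, the mitochondrial thioredoxin, from 111 ± 13.6 to 34.4 ± 6.20 CPM. TOMM34, linked to mitochondrial protein import, went from 461 ± 44.1 to 140 ± 33.0 CPM. R3HDM4 went from 78.6 ± 17.2 to 18.3 ± 3.91 CPM and S100A16 from 338 ± 40.4 to 121 ± 3.51 CPM. CFB (gene ID 629) lies on chromosome 6 from 31945944 to 31952135, and SNRPB2 (gene ID 6629) on chromosome 20 from 16714844 to 16741772.

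These 9 genes, 3 higher and 6 lower, were all that the unpaired edgeR fit called, while 1820 genes had an unadjusted p under 0.05. Unpaired log2 fold changes were 2.25 for CFB (SE 0.25, adjusted p = 0.0294), 1.47 for MGAT4B (SE 0.18, adjusted p = 0.0415) and -2.15 for SNRPB2 (SE 0.19, adjusted p = 0.0278). They were -2.10 for R3HDM4 (SE 0.24, adjusted p = 0.0294), -1.72 for TIMM17B (SE 0.18, adjusted p = 0.0294) and -1.72 for TOMM34 (SE 0.21, adjusted p = 0.0415). TXN2 changed by -1.69 (SE 0.19, adjusted p = 0.0294) and S100A16 by -1.48 (SE 0.16, adjusted p = 0.0294). SERPINA3 rose from 0.274 ± 0.110 to 6.48 ± 2.49 CPM (log2 fold change 4.52, SE 0.48, adjusted p = 0.0294), and is named after its values were seen since it lies below the level the rule asks for. The 3′ UTRs of SNRPB2, R3HDM4, TIMM17B, TXN2, S100A16 and SERPINA3 hold 1 TGGGTC each, and those of TOMM34, CFB and MGAT4B hold none. Leaving out any library or replicate number ended all 9 calls in edgeR, except that without ACSS2 shRNA replicate 3 the count was 1 higher and 5 lower, of which 1 higher and 3 lower were among the 9. DESeq2 without the block called 199 genes higher and 288 lower.

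With the replicate block, 1657 genes rose and 1608 fell, among them all 9 above. Of these, 260 rose and 258 fell at least 2-fold. The biological coefficient of variation was 26.6% unpaired and 11.8% paired. Without replicate 2 the paired counts were 664 higher and 917 lower. The authors' deposited table has 169 genes higher and 254 lower at q under 0.05, of which 421 were tested here, and all 421 were called in the same direction by the paired fit.

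Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest increases in the paired fit, listed after the data were seen, included the serpin SERPINB4, the cystatins CST1 and CST4, the BH3-only pro-apoptotic gene BMF, PIK3IP1, a negative regulator of PI3K, transglutaminase TGM2 and SHOC1. SERPINB4 rose from 1.40 ± 0.670 to 11.97 ± 5.37 CPM (log2 fold change 3.11, SE 0.23, adjusted p = 7.29e-06) and CST1 from 23.6 ± 12.2 to 229 ± 149 CPM (3.07, SE 0.32, adjusted p = 9.89e-05). CST4 rose by 2.79, BMF by 2.43, PIK3IP1 by 2.39, TGM2 by 2.27 and SHOC1 by 1.86 on the log2 scale. CST1 and CST4 differed most in pair 2 (4.39 and 3.99, against 1.96 and 1.40 in pair 1), and without replicate 2 they were 2.39 and 2.11. SERPINB4 and SERPINB3, and CST1 and CST4, are close paralogs between which reads can be shared, so which member changed is uncertain. Within the same limits the largest decreases were in SNRPB2, ARNT2, R3HDM4, FSTL3, UNG, HS1BP3, STK40 and NRM. UNG, the uracil-DNA glycosylase of base excision repair, fell from 57.6 ± 27.0 to 13.5 ± 1.23 CPM (log2 fold change -2.01, SE 0.20, adjusted p = 6.95e-05). The kinase-like gene STK40 fell from 291 ± 45.6 to 80.9 ± 32.0 CPM (-1.90, SE 0.14, adjusted p = 7.29e-06). FSTL3, a secreted activin antagonist, fell from 56.5 ± 16.8 to 14.1 ± 5.94 CPM (-2.03, SE 0.13, adjusted p = 4.25e-06). Log2 fold changes were -2.11 for ARNT2, -2.01 for HS1BP3 and -1.87 for NRM. All unpaired edgeR adjusted p values of these genes, apart from CFB, SNRPB2 and R3HDM4, were at least 0.0630. All 8 of the lower genes carry TGGGTC in the 3′ UTR, and of the 8 higher ones BMF and TGM2 do.

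**Figure D3:**
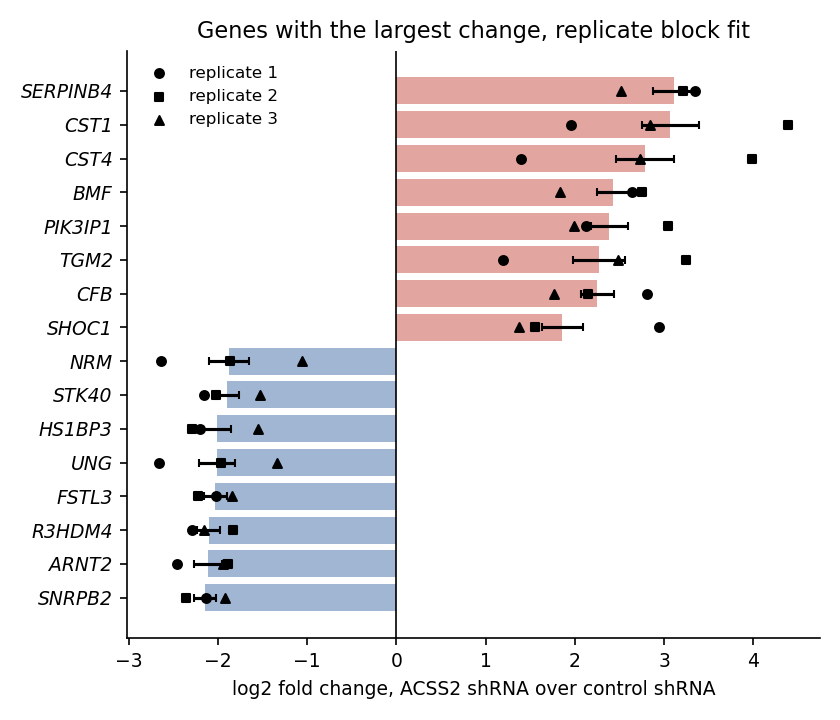
Log2 fold change of the paired fit (coloured bars, with SE) and of each replicate pair (points) for the 8 genes with the largest increase and the 8 with the largest decrease among genes with a mean of at least 5 CPM and no overlap between the groups. Bars run from 3.11 for SERPINB4 to -2.14 for SNRPB2.

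TGGGTC, chosen after the data were seen, occurs in the 3′ UTR of 26% of the 12712 tested genes with an annotated 3′ UTR. Among genes that fell in the paired fit the share was 40.8% (650 of 1592), and among those that fell at least 2-fold it was 56.6% (141 of 249). Among genes that rose it was 23.8% (388 of 1629). The median log2 fold change was -0.04 for the 3303 genes with TGGGTC and 0.04 for the 9409 genes without it. With the 3303 genes left out, the paired fit called 917 genes lower.

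**Figure D4:**
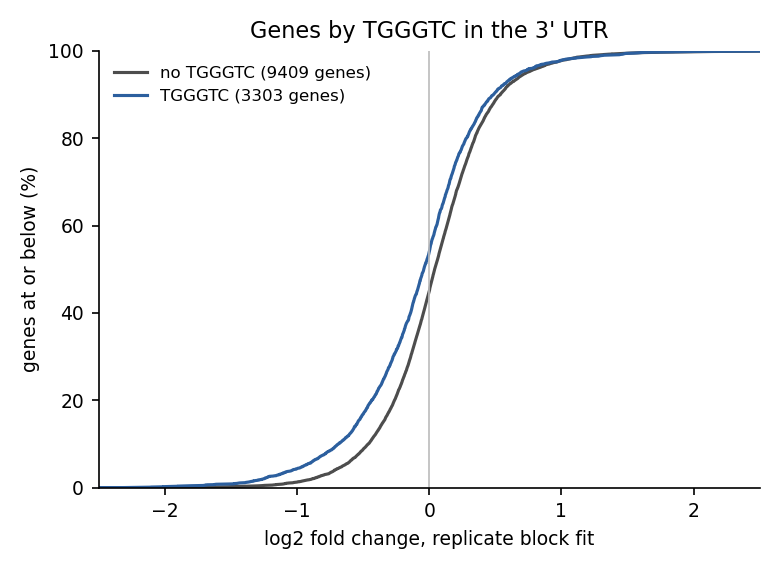
Cumulative share of genes by log2 fold change of the paired fit, for the 3303 genes with TGGGTC in the 3′ UTR and the 9409 without. Below 0 the curve of genes with TGGGTC lies to the left of the other, with medians of -0.04 and 0.04.

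All 29 mitosis genes fell in the paired fit and none passed in unpaired edgeR, with a median log2 fold change of -0.81, -0.99 and -0.48 in pairs 1, 2 and 3. TPX2, a spindle assembly factor, went from 305 ± 178 to 106 ± 36.2 CPM (-1.39, SE 0.17, adjusted p = 0.000177), CCNB2 (cyclin B2) from 54.3 ± 22.2 to 27.2 ± 7.16 CPM (-0.94, SE 0.13, adjusted p = 0.000406) and PTTG1 (securin) from 196 ± 42.2 to 115 ± 10.3 CPM (-0.75, SE 0.12, adjusted p = 0.000955). Of 35 E2F targets and DNA replication genes, 23 fell, 2 rose and 10 did not pass in the paired fit, and none passed in unpaired edgeR. PCNA, the replication clamp, went from 72.4 ± 32.1 to 37.8 ± 5.55 CPM (-0.85, SE 0.16, adjusted p = 0.00262) and CDC6, a licensing factor, from 41.7 ± 25.8 to 16.3 ± 6.17 CPM (-1.24, SE 0.17, adjusted p = 0.000344). E2F7, a repressor of E2F targets, rose from 95.5 ± 12.1 to 143 ± 24.7 CPM (0.58, SE 0.12, adjusted p = 0.00443). RB1, the retinoblastoma tumour suppressor, fell from 33.2 ± 10.1 to 15.9 ± 1.92 CPM (-1.03, SE 0.14, adjusted p = 0.000415). The groups overlap in TPX2, CCNB2, PCNA and CDC6, but not in PTTG1, E2F7 and RB1. For TPX2, control replicate 3 (133 CPM) lies below ACSS2 shRNA replicate 1 (146 CPM).

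Camera called the mitosis list lower (adjusted p = 2.13e-06 unpaired and 2.40e-14 paired), but adjusted p = 0.844 with an estimated correlation unpaired and 0.695 paired. It called the E2F target list lower as well (adjusted p = 0.00506 unpaired and 1.39e-06 paired), with adjusted p = 0.972 with an estimated correlation unpaired and 0.871 paired. With fry neither list passed (adjusted p = 0.696 unpaired and 0.118 paired for mitosis, 0.844 and 0.361 for E2F targets). The unpaired E2F target call was lost without replicate 2 (adjusted p = 0.0502), without control replicate 1 (0.903) and without ACSS2 shRNA replicate 3 (0.355), and the paired medians were -0.86, -0.57 and -0.08 in pairs 1, 2 and 3. With the block 29 mitosis genes fell adjusted over the list alone, as did 25 E2F targets, with 2 higher. No member of either list passed in unpaired edgeR, over all genes or adjusted over the list alone, while unpaired DESeq2 called TPX2 (-1.56, adjusted p = 0.0122) and PTTG1 (-0.80, 0.0158), and RB1 as well (-1.10, 0.00880). Of the 13 E2F and RB family members 2 rose and 3 fell in the paired fit, the same counts adjusted over the list alone, and unpaired 1 fell adjusted over the list alone. That list was not called (adjusted p = 0.973 unpaired and 0.828 paired, direction lower, paired median 0.00 and mean -0.14). TGGGTC occurs once in the 3′ UTR of TPX2 and of CDC6 and in 2 copies in that of RB1, and in 4 of the 29 mitosis genes.

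Of 22 ribosomal protein genes 11 fell, none rose and 11 did not pass in the paired fit, and none passed in unpaired edgeR. Adjusted over the list alone 18 fell in the paired fit. RPL8 went from 2062 ± 92.5 to 1435 ± 257 CPM (-0.54, SE 0.15, adjusted p = 0.0179), RPL5 from 1255 ± 116 to 911 ± 162 CPM (-0.47, SE 0.13, adjusted p = 0.0192) and RPS12 from 277 ± 33.1 to 200.04 ± 38.0 CPM (-0.48, SE 0.11, adjusted p = 0.00915). Ribosomal protein genes with RPL or RPS symbols, beyond this list as well, took 7.97%, 8.66% and 9.03% of counts in control replicates 1, 2 and 3, and 5.57%, 6.65% and 7.94% in ACSS2 shRNA replicates 1, 2 and 3. Of 25 oxidative phosphorylation genes 6 fell and none rose in the paired fit, with the same counts adjusted over the list alone. Examples were the ATP synthase subunits ATP5MC1 (138 ± 16.5 to 96.0 ± 8.29 CPM, log2 fold change -0.52) and ATP5F1B (672 ± 61.3 to 510 ± 29.3 CPM, -0.39) and the cytochrome c oxidase subunit COX5A (179 ± 20.8 to 128 ± 4.87 CPM, -0.48).

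The ribosomal protein list was called lower (adjusted p = 1.62e-06 unpaired and 1.99e-06 paired), with adjusted p = 0.616 with an estimated correlation unpaired and 0.871 paired. The oxidative phosphorylation list was called lower (adjusted p = 0.00498 unpaired and 0.0117 paired), with adjusted p = 0.161 with an estimated correlation unpaired and 0.695 paired, and lost with the length and GC correction (adjusted p = 0.0643 unpaired and 0.0935 paired). Fry gave adjusted p = 0.203 unpaired and 0.193 paired for ribosomal proteins, and 0.0337 and 0.0831 for oxidative phosphorylation. No member of these lists passed in unpaired edgeR. Without replicate 2 the paired calls of RPL8 (-0.58, adjusted p = 0.128), RPL5 (-0.46, 0.186), ATP5MC1 (-0.48, 0.0618), COX5A (-0.46, 0.0929) and ATP5F1B (-0.41, 0.202) were lost, with log2 fold changes near those of all 3 pairs. That of ATP5F1B was also lost without replicate 3 (-0.45, 0.0531) and with limma on log2 TPM (-0.29 with either pseudocount, 0.0521 and 0.0524).

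Of 24 autophagy and lysosome genes 12 rose, none fell and 12 did not pass in the paired fit, among them ULK1, the autophagy-initiating kinase (52.0 ± 7.33 to 108 ± 7.08 CPM, log2 fold change 1.06), and the lysosomal proteases CTSL (59.1 ± 14.6 to 112 ± 15.8 CPM, 0.95) and CTSB (422 ± 83.2 to 755 ± 85.7 CPM, 0.85). Of 10 replication-dependent histone genes 7 rose, none fell and 3 did not pass. Those that rose included H2BC5 (18.2 ± 2.53 to 35.6 ± 1.25 CPM, 0.98), H1-2 (20.7 ± 2.01 to 33.4 ± 2.81 CPM, 0.69) and H2AC6 (1.75 ± 0.408 to 4.83 ± 1.99 CPM, 1.43). Because mRNA was enriched with oligo(dT) beads, these values cover polyadenylated histone transcripts only. Whether histone mRNA as a whole rose was not tested. Of 20 unfolded protein response genes 12 rose, 1 fell and 7 did not pass. HERPUD1, which acts in degradation of misfolded proteins at the endoplasmic reticulum, went from 109 ± 37.0 to 203 ± 47.4 CPM (0.93), the co-chaperone DNAJB9 from 7.58 ± 2.82 to 14.7 ± 1.25 CPM (1.00) and PDIA4 from 189 ± 5.29 to 262 ± 25.5 CPM (0.47). The broader hallmark set for this response, looked at after the data were seen, did not move this way: of 106 genes 13 rose and 15 fell, with a camera direction of lower (adjusted p = 0.620 unpaired and 0.876 paired). Of 24 mesenchymal and matrix genes 12 rose, none fell and 12 did not pass, with COL5A1 (63.0 ± 11.5 to 154 ± 38.1 CPM, 1.28), COL1A1 (15.1 ± 2.54 to 36.4 ± 13.5 CPM, 1.22) and the collagen cross-linking enzyme LOX (177 ± 47.8 to 310 ± 34.5 CPM, 0.84).

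Camera called the autophagy, histone, unfolded protein response and matrix lists higher, but only with the preset correlation. Adjusted p was 0.000128 unpaired and 2.17e-05 paired for autophagy and lysosome, 0.000128 and 1.22e-05 for histones, 0.000254 and 0.000363 for the unfolded protein response and 0.000435 and 0.00165 for matrix genes. With an estimated correlation no camera call held in either fit. In the same order, adjusted p was 0.210, 0.161, 0.161 and 0.161 unpaired, and 0.695, 0.695, 0.695 and 0.806 paired. Fry passed each of these lists unpaired (adjusted p = 0.0454, 0.0467, 0.0337 and 0.0349) and none paired (0.0787, 0.0787, 0.0787 and 0.118). Adjusted over the list alone, 16 autophagy and lysosome, 7 histone, 15 unfolded protein response and 12 matrix genes rose in the paired fit, and 1 unfolded protein response gene fell. In unpaired edgeR no member passed over all genes, and 3 autophagy and lysosome, 4 histone and 2 matrix genes rose adjusted over the list alone. Unpaired DESeq2 called ULK1 (adjusted p = 5.44e-05), CTSL (0.00880), CTSB (0.0132), H2BC5 (0.000807), H1-2 (0.0362), H2AC6 (0.0340), COL5A1 (0.000262) and COL1A1 (0.00535) higher, and with the length and GC correction H2BC5 passed in unpaired edgeR (0.0476). The paired call of PDIA4 was lost without replicate 2 (0.48, adjusted p = 0.0818) and without replicate 3 (0.40, adjusted p = 0.0673), and without replicate 1 DNAJB9 was 0.62 (adjusted p = 0.0230).

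**Figure D5:**
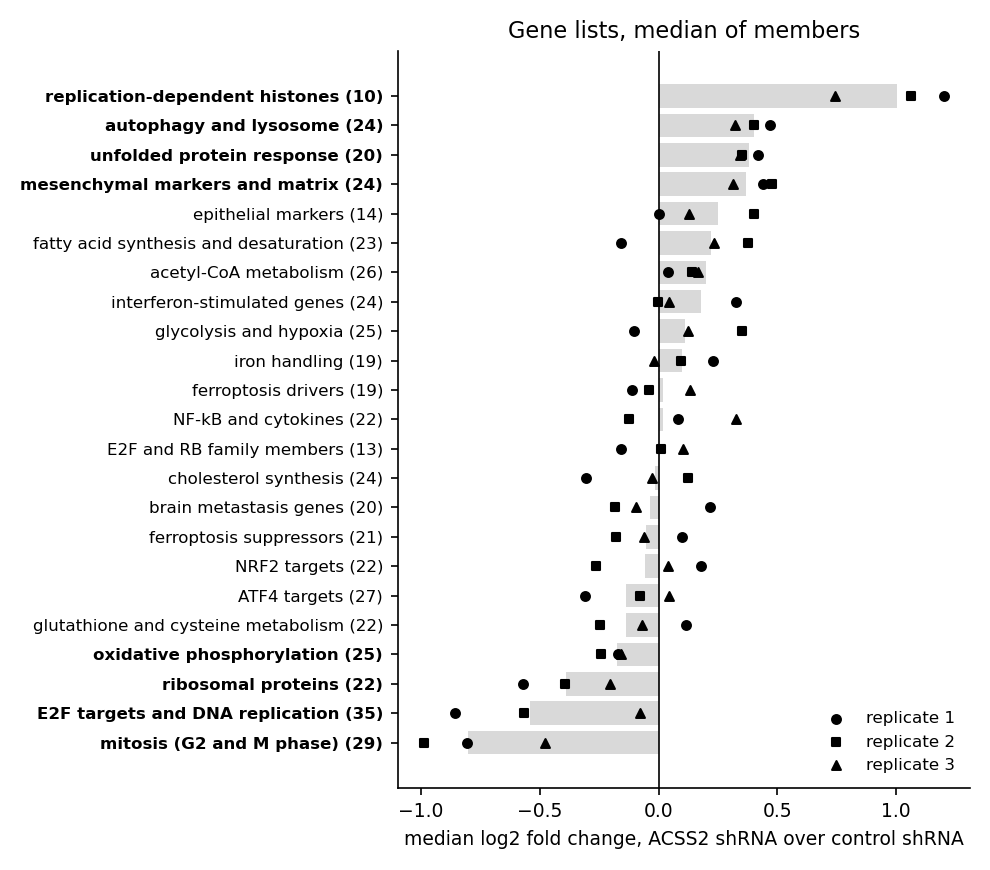
Median log2 fold change of each list reported here in the paired fit (bars) and in each replicate pair (points), with the number of genes tested in parentheses and lists called by camera with the preset correlation in bold. The mitosis medians lie between -0.99 and -0.48, and the histone medians between 0.74 and 1.20.

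Ferroptosis genes moved in both directions. Over all genes the paired fit called 1657 of 13003 higher and 1608 lower, so calls in both directions are not particular to these genes. Of 21 ferroptosis suppressors 3 rose and 4 fell in the paired fit. FTH1, the ferritin heavy chain that stores iron, rose from 2291 ± 364 to 3527 ± 575 CPM (log2 fold change 0.62, SE 0.14, adjusted p = 0.00648), while DHODH, a mitochondrial enzyme that reduces ubiquinone, fell from 15.4 ± 1.94 to 8.59 ± 2.07 CPM (-0.86, SE 0.15, adjusted p = 0.00169) and PRDX6 fell from 177 ± 6.08 to 132 ± 11.3 CPM (-0.42, SE 0.11, adjusted p = 0.0168). Of 19 ferroptosis drivers 3 rose and 3 fell. NCOA4, the receptor for ferritin autophagy, fell from 98.2 ± 12.4 to 59.4 ± 11.1 CPM (-0.73, SE 0.12, adjusted p = 0.00120), and CHAC1, a glutathione-degrading enzyme, rose from 12.2 ± 3.65 to 22.5 ± 3.38 CPM (0.91, SE 0.16, adjusted p = 0.00143). Of 22 glutathione and cysteine genes 4 rose and 3 fell. Besides CHAC1 they included OPLAH (10.7 ± 1.88 to 17.4 ± 1.24 CPM, 0.72), higher, and AHCY (333 ± 18.7 to 248 ± 41.7 CPM, -0.44), lower. The 3′ UTRs of NCOA4 and AHCY hold 1 TGGGTC each.

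None of these 3 lists was called, with adjusted p = 0.839 unpaired and 0.765 paired for suppressors, 0.952 and 0.944 for drivers, and 0.839 and 0.828 for glutathione and cysteine. Adjusted over the list alone, 4 suppressors rose and 4 fell, 3 drivers rose and 4 fell, and 4 glutathione genes rose and 4 fell in the paired fit. Among these genes none passed over all genes in unpaired edgeR, though unpaired DESeq2 called NCOA4 (adjusted p = 0.0373) and DHODH (0.0475) lower, and in unpaired edgeR 2 drivers fell adjusted over the list alone. The glutathione list had a paired median of -0.14 and a mean of 0.01 with a test direction of lower, and the drivers had an unpaired median of 0.01 and a mean of 0.00 (-0.002) with a test direction of higher. Without replicate 2 the paired calls of FTH1 (0.55, adjusted p = 0.1795), PRDX6 (-0.44, 0.105) and AHCY (-0.44, 0.141) were lost, with log2 fold changes near those of all 3 pairs, and that of AHCY also without replicate 1 (-0.35, 0.0524).

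Lists of metabolic, iron, NRF2 and ATF4 genes gave mixed counts, apart from glycolysis and hypoxia. Some members are also in the ferroptosis lists, such as FTH1 and NCOA4 in iron handling, so these counts are not separate from those above. ACAT2, a cytosolic acetoacetyl-CoA thiolase, fell from 52.7 ± 6.29 to 22.8 ± 3.05 CPM (log2 fold change -1.21, SE 0.14, adjusted p = 0.000137 paired), and the sterol isomerase EBP fell from 13.3 ± 2.88 to 6.13 ± 0.744 CPM (-1.11, SE 0.19, adjusted p = 0.00151). LPIN1, a phosphatidate phosphatase, rose from 110.0 ± 10.00 to 192 ± 35.8 CPM (0.79, SE 0.12, adjusted p = 0.000654), the ferric reductase CYBRD1 from 47.4 ± 5.93 to 78.4 ± 7.56 CPM (0.73, SE 0.12, adjusted p = 0.00140) and the hypoxia gene BNIP3 from 205 ± 29.3 to 273 ± 17.7 CPM (0.43, SE 0.13, adjusted p = 0.0283). Of 26 acetyl-CoA genes 3 rose and 5 fell in the paired fit, 3 of 24 cholesterol synthesis genes rose and 5 fell, and 7 of 23 fatty acid genes rose and 5 fell. Of 25 glycolysis and hypoxia genes 11 rose and none fell, and of 19 iron handling genes 5 rose and 2 fell. The broader hallmark sets were looked at after the data were seen. Of 173 glycolysis genes there 26 rose and 26 fell (camera adjusted p = 0.813 unpaired and 0.882 paired). Of 151 hypoxia genes 36 rose and 16 fell (0.0430 and 0.0549, or 0.778 and 0.803 with an estimated correlation). Of 22 NRF2 targets 3 rose, among them the transporter ABCC3 (5.09 ± 1.51 to 12.3 ± 5.26 CPM, 1.23, with 1 TGGGTC), and 2 fell. Of 27 ATF4 targets 6 rose, among them VLDLR (15.4 ± 2.05 to 28.0 ± 3.27 CPM, 0.86), and 5 fell.

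No list of this group was called, with adjusted p of 0.906 unpaired and 0.731 paired for acetyl-CoA, 0.839 and 0.765 for cholesterol, 0.660 and 0.674 for fatty acids, 0.189 and 0.218 for glycolysis, 0.660 and 0.731 for iron, 0.952 and 0.982 for NRF2 and 0.714 and 0.731 for ATF4. Adjusted over the list alone, the paired fit had 6 higher and 5 lower for acetyl-CoA, 3 and 5 for cholesterol, 8 and 5 for fatty acids, 11 and 0 for glycolysis, 5 and 2 for iron, 3 and 2 for NRF2 and 7 and 8 for ATF4. Unpaired edgeR called no member over all genes, and adjusted over the list alone it had 2 acetyl-CoA genes, 1 cholesterol, 2 iron and 2 ATF4 genes lower and 1 fatty acid, 1 iron and 1 ATF4 gene higher. Unpaired DESeq2 called ACAT2 (adjusted p = 7.17e-06) and EBP (0.00407) lower and LPIN1 (0.0119), CYBRD1 (0.0193), ABCC3 (0.0383) and VLDLR (0.0137) higher, and ACAT2 passed in unpaired edgeR with no low-count filter (0.0445) and with the length and GC correction (0.0394). The NRF2 list had a paired median of -0.06 and a mean of 0.06 with a test direction of higher. The glycolysis list was called higher without replicate 1 (adjusted p = 0.00301 unpaired and 0.00474 paired), without control replicate 1 (0.000226) and without ACSS2 shRNA replicate 2 (0.0389), and the fatty acid list without replicate 1 (0.0449 unpaired and 0.0410 paired). With all libraries, both lists had adjusted p = 0.972 with an estimated correlation unpaired and 0.948 paired. Without replicate 2 the paired call of BNIP3 was lost (0.25, adjusted p = 0.434) and ABCC3 was 0.79 (adjusted p = 0.0352).

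Signalling and metastasis genes included IL11, a cytokine of the IL-6 family, which fell from 61.8 ± 15.7 to 26.2 ± 4.94 CPM (log2 fold change -1.23, SE 0.15, adjusted p = 0.000197 paired) and has 3 TGGGTC in its 3′ UTR. IRF9, a subunit of the interferon-activated factor ISGF3, rose from 22.4 ± 3.50 to 39.4 ± 7.17 CPM (0.81, SE 0.15, adjusted p = 0.00200), the tight junction gene CLDN4 from 24.0 ± 4.59 to 46.1 ± 6.01 CPM (0.95, SE 0.15, adjusted p = 0.00106) and the laminin gene LAMA4 from 55.2 ± 3.08 to 88.2 ± 5.95 CPM (0.68, SE 0.11, adjusted p = 0.00135). Of 22 NF-kB and cytokine genes 5 rose and 4 fell in the paired fit, 7 of 24 interferon-stimulated genes rose and 1 fell, 5 of 14 epithelial markers rose and none fell, and 5 of 20 brain metastasis genes rose and 2 fell. Adjusted over the list alone these counts were 7 and 4, 9 and 2, 5 and 0, and 5 and 2. No member passed over all genes in unpaired edgeR, and adjusted over the list alone 1 NF-kB gene, 1 epithelial marker and 1 brain metastasis gene were higher and 1 NF-kB gene was lower. Unpaired DESeq2 called IL11 lower (adjusted p = 0.000609) and IRF9 (0.0343), CLDN4 (0.00520) and LAMA4 (0.0122) higher. The lists were not called (adjusted p = 0.952 unpaired and 0.828 paired for NF-kB, 0.625 and 0.340 for interferon, 0.119 and 0.218 for epithelial markers, 0.906 and 0.828 for brain metastasis), though epithelial markers were called higher with a filter of 5 CPM (0.0142 unpaired and 0.0144 paired) and with fry unpaired (0.0340) but not paired (0.325). For epithelial markers adjusted p = 0.360 with an estimated correlation unpaired and 0.871 paired. The NF-kB list had a paired median of 0.02 and a mean of -0.06, and the brain metastasis list a paired median of -0.04 and a mean of 0.11, both with a test direction of higher.

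Markers of other cell types ranged from below the level of testing to 642 CPM (CD68), and those that passed in the paired fit went in both directions. Over all genes the paired fit called 3265 of 13003. Of 7 neuron and glia markers tested 1 rose (ALDH1L1, log2 fold change 0.58) and 3 fell (SYT1 -1.44, RBFOX3 -0.82 and MBP -0.41, the last from 151 to 117 CPM) in the paired fit. Of 4 immune markers CD14 (1.30) and CD74 (0.88) rose, and the most abundant, CD68, did not pass (642 and 573 CPM, adjusted p = 0.359). Of 6 endothelial markers CDH5 (1.79) and KDR (0.87) rose, and the most abundant, TIE1 (336 and 398 CPM, adjusted p = 0.117) and ESAM (216 and 185 CPM, adjusted p = 0.310), did not pass. Of 4 fibroblast and pericyte markers ACTA2 fell from 15.1 to 8.43 CPM (-0.94). Red blood cell genes were too low to test, with HBA1 at 0.389 CPM in both groups. None of these markers passed in the unpaired edgeR fit, where the smallest adjusted p was 0.217 (CDH5).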

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

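The length and GC correction, leaving out genes with TGGGTC and all alternatives to the paired fit were chosen only after the results were seen. For the unpaired fit (3 higher, 6 lower), DESeq2 called 199 higher and 288 lower, no low-count filter 12 and 27, the replicate block 1657 and 1608, the length and GC correction 20 and 57, and leaving out genes with TGGGTC, or an adjusted p under 0.01, 0 and 0. Limma on log2 TPM called 6 higher with either pseudocount. Without a library or replicate number the counts were 0 to 1 higher and 0 to 5 lower. Fewer libraries and fewer degrees of freedom are part of those settings, and the cause of the other shifts was not tested. With the block ACSS2 was -1.309 and E2F1 -0.522, both past the threshold. For the paired fit, an adjusted p under 0.01 left 756 higher and 795 lower, a 2-fold change 260 and 258, and leaving out a replicate number 664 to 1555 higher and 917 to 1554 lower. Limma on log2 TPM called 2302 higher and 1071 lower, or 2269 and 1055, by pseudocount, and leaving out genes with TGGGTC 1208 and 917, with fewer genes tested. ACSS2 missed the threshold with DESeq2 and the block (-1.382). E2F1 missed it with limma on log2 TPM (-0.379 and -0.391), without replicate 1 (-0.293) and without replicate 2 (-0.562), and passed without replicate 3 (-0.739). SLC7A11 passed with no filter (-0.502) and the length and GC correction (-0.549), and ranged from -0.825 to -0.216 without a replicate. The cause was not tested. Lists called higher, of which the report describes 4, went from 5 to 0 with an estimated correlation in both fits, and to 1 with fry paired. Lists called lower went from 4 to 0 with an estimated correlation in both fits, to 1 with fry unpaired and to 0 with fry paired. No called list changed direction under any alternative run. Over named genes, 1030 of 1179 unpaired values kept their direction and side of the threshold, 71 no longer passed, 78 passed and 0 changed sign as calls. All 71 losses fell on the named genes that the unpaired fit had called, each lost in 8 to 10 of 20 settings. The other named genes had no unpaired call to lose. In the paired fit 909 of 935 kept both, 21 no longer passed, 5 passed and 0 changed sign as calls. Scaling moved the median log2 fold change of all genes from 0.02 to between -0.01 and 0.08, and 50.8% of paired calls were higher, against 60.3% with total counts and 45.7% with DESeq2 size factors. What depth limits was not tested.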

Other observations

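The hallmark sets, the protocadherin genes, and the tests of TGGGTC and of length and GC content in mitosis genes were chosen only after the results were seen. Clustered protocadherins, adhesion proteins encoded on chromosome 5, were higher with the ACSS2 shRNA. In the paired fit 12 of 13 gamma cluster genes (141330685 to 141512981) and 6 of 9 beta cluster genes (141094380 to 141248234) rose and none fell, while in unpaired edgeR none passed. Median log2 fold changes were 1.46 for gamma and 1.11 for beta genes, and 12 gamma genes and 7 beta genes were higher in all 3 pairs. They were picked because they were seen to be higher, so no set test is given. Median levels were 1.68 CPM for gamma and 2.34 CPM for beta genes, and gamma genes share 3′ exons, so their reads are not independent.

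Of 50 hallmark sets in the deposited annotation, camera called 4 higher and 5 lower in the paired fit. None held with an estimated correlation, where the smallest adjusted p was 0.803 paired and 0.464 unpaired. In the E2F target set 100 of 188 genes fell and 1 rose (adjusted p = 1.46e-15), in the G2M checkpoint set 85 of 183 fell and 6 rose (5.14e-09), and in the first MYC target set 68 of 196 fell and 0 rose (1.04e-11). In the set of IL-6, JAK and STAT3 signalling 19 of 55 genes rose and 7 fell (0.00717).

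Genes lower with the ACSS2 shRNA carried TGGGTC in the 3′ UTR more often than others, and a candidate explanation is seed pairing of a hairpin with unintended transcripts. Of 16380 7-mers, TGGGTCT had the strongest association (effect -0.20, SE 0.0138, 1483 genes, Bonferroni-adjusted p = 1.22e-44), and it occurs in the last of 18 exons of ACSS2, in the 3′ UTR (chromosome 20, 34927673 to 34927679, plus strand), as 16.2% of all 7-mers occur somewhere in that mRNA. In all, 29 7-mers with a negative effect passed the Bonferroni threshold, which 1 7-mer passed with none planted. Only those down to GGGTCAT (t = -8.51) went past the highest absolute t of the permutations, as the next, TCTGGGT, had t = -6.97. Most of these contain or overlap TGGGTC. AGAAGCC (-0.12, t = -9.03) is among them and does not overlap it. AGAAGCC is absent from the ACSS2 mRNA, though its reverse complement is present, so TGGGTC is not the only sequence associated with lower levels. Sites paired by the second strand of a hairpin would be reverse complements of ACSS2 sequence. AGAAGCC is therefore no evidence against the hairpin explanation, and whether it stems from that strand was not tested. Against chance ordering of genes, 0 of 100 permutations reached the size of the observed t of -14.75 (their highest absolute t was 7.91), and against length and GC bias, the effect was -0.197 after the correction and -0.24, -0.21 and -0.15 in pairs 1, 2 and 3. Hairpin sequences and their number were not used here, so a microRNA with the same seed and effects that follow from lower ACSS2 stay open, for SLC7A11, RB1 and the other genes given with TGGGTC in the report.

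Mitosis genes were lower in every pair, with a highest median of -0.48, which argues against a single pair as the source. The share with TGGGTC was 13.8% (4 of 29), below the 26% of all tested genes, which argues against direct pairing through TGGGTC as the cause of the whole pattern, while other seeds were not tested. After the length and GC correction the median was -0.782 (before -0.80, SD over pairs 0.240), which argues against that trend. Slower division after lower ACSS2, or after lower levels of unintended targets, may each give this pattern. The labels name no rescue that would part them. Mitosis genes also differed between control replicates 1, 2 and 3: TPX2 had 489, 293 and 133 CPM, CCNB2 73.4, 59.5 and 29.9, and PTTG1 200, 236 and 152. What made replicates differ was not tested, so differences between libraries apart from the hairpin stay open too. The medians per pair (-0.81, -0.99 and -0.48) did not rank with the ACSS2 log2 fold changes (-2.76, -0.49 and -0.88).

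Ribosomal protein genes had a median log2 fold change of -0.39, and -0.327 after the length and GC correction (pairs -0.50, -0.29 and -0.17, SD 0.163), which argues against that trend as the whole cause. A change in growth state could give the same pattern, and was not tested.

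Of the 10 splits of the 6 libraries into groups of 3, 1 (the real one) called 9 or more genes in the unpaired fit, and the highest other split called 1. Of the 4 splits that part every pair, 1 (the real one) called 3265 or more in the paired fit, and the highest other called 0. The splits are too few for a share under 0.05. In the other splits the difference between the groups adds to the residual spread, which lowers their calls. Their counts therefore do not show how many genes would be called without a group difference.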
